A study of Mus musculus with 10 samples.

How the data were processed

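The data were 10 Illumina mouse whole-genome expression arrays, 1 per RNA sample: 2 of undifferentiated MSC and 1 each of the 8 other populations. Samples were placed in groups from their labels alone, and no sample was left out. The deposited scanner table held, per the file headers, a bead-summary intensity and a detection p-value for each of 45281 probes on each array. How the authors made these values is not given in the sources used here. In the values, the deposited intensities of 8 arrays already shared 1 distribution, as after quantile normalisation, with a mean near 538, while the differentiated and reprogrammed osteocyte arrays stood on other distributions with means of 324 and 413. The 75th percentile over background was 1.84 and 1.99 on those arrays and from 2.28 to 2.36 on the others, so scale and osteocyte lineage could not be told apart. The p-value of each intensity is, from its steps, a rank against negative control beads made by the scanner software before the table was deposited.

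The deposited value table of the series was linear for 8 arrays and log2 for the osteocyte pair, and the log2 values of the pair shared 1 distribution as deposited. For the pair, values followed the scanner table by probe ID, with Spearman rho of 1.00 and 0.998. For the other 8 columns rho by probe ID lay from -0.00745 to -0.00155, and each of 45281 lines matched a single scanner probe by its rank on all 8 arrays, within 1 rank, while 1 line carried that probe's ID. The value table was therefore not used by its own IDs. Its linear values, which are background-subtracted and not normalised between arrays, served as an alternative after that rank match.

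Background correction used normexp with parameters from the detection p-values and an offset of 16, then quantile normalisation and log2, by neqc of limma 3.58.1 in R 4.3.3. A probe was detected on an array at a detection p-value under 0.01. Detected probes numbered 14896 to 16737 (32.9% to 37.0%), with 15655 on MSC 1 and 16105 on MSC 2. Gene symbols came from the array annotation: 34885 probes had 1 symbol, 18 several and 10378 none, covering 19057 genes. Each gene was read from its probe of highest mean intensity.

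Common changes were fitted with lmFit and eBayes of limma, on probes detected on at least 2 arrays of the fit. Reprogrammed minus differentiated used 6 arrays with lineage as a block and 2 residual degrees of freedom. Differentiated and reprogrammed populations against MSC used 1 fit of 8 arrays with 5 residual degrees of freedom. P values were adjusted by Benjamini-Hochberg and called under 0.05. The in vivo arrays stayed outside these fits, as a different origin and treatment. Other populations and single pairs were described without a test: a probe counted at 2-fold or more from both MSC arrays, or from the other array of the pair, with detection on the higher side. Where a gene was not detected on 1 side, or on part of the arrays of the lower side, each such array was set to the lowest log2 value among detected probes of its array, or to its own value where that was higher.

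Gene lists were fixed before the values were seen: adipocyte, chondrocyte, osteoblast and osteocyte, stromal, endothelial, macrophage, osteoclast, erythroid, neutrophil and B cell, and skeletal muscle markers, smooth muscle and pericyte genes, pluripotency, cell cycle, DNA methylation, germline, imprinted, interferon-stimulated, immediate-early, p53 target, extracellular matrix, cholesterol synthesis, hypoxia and glycolysis, unfolded protein response, Hox, sex-linked and housekeeping genes, 26 in all. Lists with at least 3 measured genes were tested with camera (preset correlation 0.01, and an estimated correlation), and with fry, which asks whether the genes move on balance one way, all in limma. Members were also counted with p values adjusted over the list alone. In single comparisons a list median was placed among 10000 random lists of the same size, matched on 20 bins of expression, from 11686 genes.

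Genes were named by a rule fixed before the values were seen. It took the 12 largest rises and falls among genes that passed with the same direction in 3 pairs, filled to 8 by the smallest p, 8 per direction for tests against MSC, and 5 per direction for single comparisons, with predicted genes passed over. It added up to 4 members of each list, Pdgfra, Pdgfrb, the DNA methyltransferases and the sex-linked genes. Other genes with a called probe are named outside this rule.

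The tests were tried on simulated data of the same layout with 200 changed probes. Noise was drawn independently for each probe, with 1 spread for all groups, unlike the real arrays, where genes of a list move together. The test common to 3 lineages found 4.48%, 50.7% and 100% of changes of 1, 2 and 4 log2 units, with 10 false calls, and the test of differentiated populations against MSC 0%, 17.9% and 93.9%, with 8. Random lists of 20 genes stood above the 99th percentile in 1 of 40 cases unshifted, 38 with a shift of 1 log2 unit and 40 with a shift of 2.

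Alternatives were no background correction, normexp with an offset of 50 in place of negative controls, 75th percentile scaling and other detection filters. Without background correction 50 was added to each scanner intensity before log2. Further alternatives were an intensity trend, 1 probe per gene, other blocks, samples and fold limits, and each lineage or MSC array left out. Added after the values were seen were the value table intensities matched by rank and a batch term for the osteocyte pair. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.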

Results

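Expression was measured on 10 mouse whole-genome bead arrays with 45281 probes each. Cultured mesenchymal stem cells (MSC), the multipotent stromal cells of bone and marrow, stood on 2 arrays. Each of 8 other populations stood on 1 array: differentiated adipocytes, chondrocytes and osteocytes, the reprogrammed population named for each of these lineages, osteocytes derived in vivo, and treated osteocytes derived in vivo. The labels used here do not name the treatment. Probes detected at a p-value under 0.01 numbered 14896 on the differentiated adipocyte array and 16737 on the reprogrammed chondrocyte array, with the other arrays between. The number of arrays limits the precision of every value, and only the MSC had a replicate. Values are log2 intensities after background correction and quantile normalisation. Where a gene was not detected on 1 side of a comparison, or on part of the arrays of the lower side, its fold is a lower limit, given beside the fitted log2 value in tests and taken against the lowest value among the detected probes of each array that lacked it. Genes named as members of a list carry the fitted value alone.

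The overall similarity of the arrays addressed how near each reprogrammed population lay to MSC and to its population of origin. Across 22172 probes detected on at least 1 array, reprogrammed adipocytes correlated with MSC 2 at r = 0.988, with MSC 1 at 0.942 and with differentiated adipocytes at 0.870. Reprogrammed chondrocytes correlated with MSC 2 at 0.990, with MSC 1 at 0.933 and with differentiated chondrocytes at 0.819. Reprogrammed osteocytes correlated with MSC 1 at 0.971, with MSC 2 at 0.965 and with differentiated osteocytes at 0.936. The MSC arrays correlated with each other at 0.952, and differentiated osteocytes with MSC 1 at 0.959. Differentiated chondrocytes were nearest to in vivo osteocytes, at 0.947. Treated in vivo osteocytes correlated with reprogrammed chondrocytes at 0.919 and with untreated in vivo osteocytes at 0.855. Probes are not independent replicates, so no test was made of these values.

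**Figure D1:**
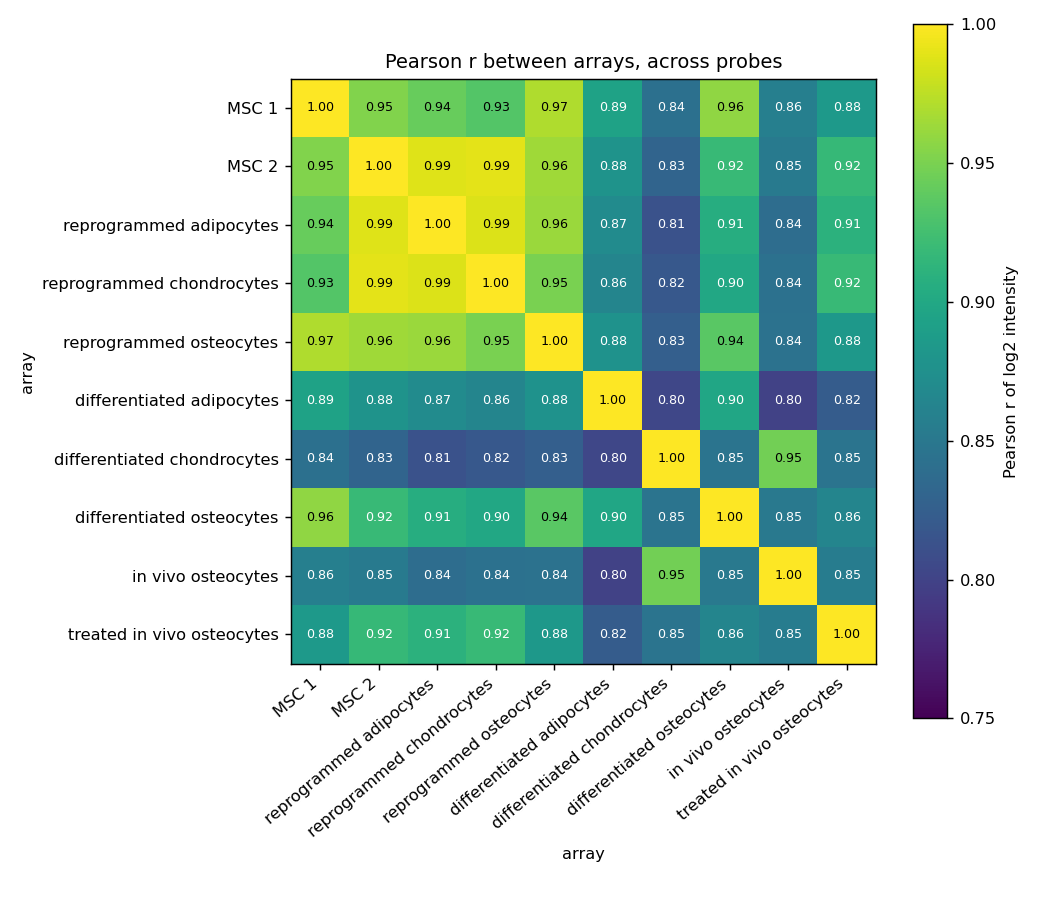
Pearson r of log2 intensity for each pair of arrays, across the 22172 probes detected on at least 1 array, with arrays on both axes and r as colour and number. Reprogrammed adipocytes and chondrocytes reached 0.988 and 0.990 with MSC 2, and differentiated chondrocytes reached 0.947 with in vivo osteocytes.

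The change common to the adipocyte, chondrocyte and osteocyte lineages on reprogramming was tested over 3 pairs of arrays, with lineage as a block. Serpina3n, a secreted serine protease inhibitor, fell by 8.03 ± 0.63 on the log2 scale (SE, 3 pairs), at least 139-fold. Sult1a1, a phenol sulfotransferase, fell by 7.81 ± 0.50, at least 138-fold, and Scara5, a ferritin receptor, fell by 6.49 ± 0.50, at least 55.0-fold. Sprr1a, a protein of the cornified envelope, rose by 4.82 ± 0.40, at least 19-fold. Dlk1, an imprinted inhibitor of adipocyte differentiation, rose by 4.47 ± 0.50, at least 20.5-fold. The adjusted p was 0.034 for Serpina3n, Sult1a1, Scara5 and Sprr1a and 0.047 for Dlk1, and each moved the same way in 3 of 3 pairs.

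Hsd11b1, which makes active glucocorticoid from its inactive form, fell by 5.05 ± 0.61 (SE). Fkbp5, a co-chaperone of the glucocorticoid receptor, fell by 4.09 ± 0.39, and Vldlr, a lipoprotein receptor, fell by 4.44 ± 0.36. Porcn, the acyltransferase that lipidates Wnt proteins, fell by 3.92 ± 0.34, and Selenop, the plasma selenium carrier, by 3.72 ± 0.41. Ccdc3, Ifi207, Map7d2 and Fmo1 changed by -4.65, -4.39 (at least 15.3-fold), -4.34 (at least 11.4-fold) and -3.94. Genes that rose included parts of the mitotic apparatus: Kif11, a spindle kinesin, by 4.10 ± 0.40, at least 9.83-fold, Ckap2l, a spindle protein, by 3.81 ± 0.42, at least 9.19-fold, and Cenph, a centromere protein, by 3.55 ± 0.38, at least 7.05-fold. Lockd, a long non-coding RNA, rose by 3.73 ± 0.45, at least 7.40-fold, and Megf10, an engulfment receptor, by 3.14 ± 0.37, at least 5.31-fold. Nefm, a neurofilament subunit, lay 3.35 ± 0.42 higher, at least 7.94-fold, and did not pass (adjusted p = 0.053). Other genes with a probe past the threshold were Tns1, Fgfr2, Rab3d, Nrap and Tsc22d3, which fell, and Bub1b, Kif23, Kif4, Cdc20, Spc24, Tyms, Gins2, Shmt2, H2ac12 and H2ac13, which rose. For these last 10 the probe that passed was not the gene's brightest.

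**Figure D2:**
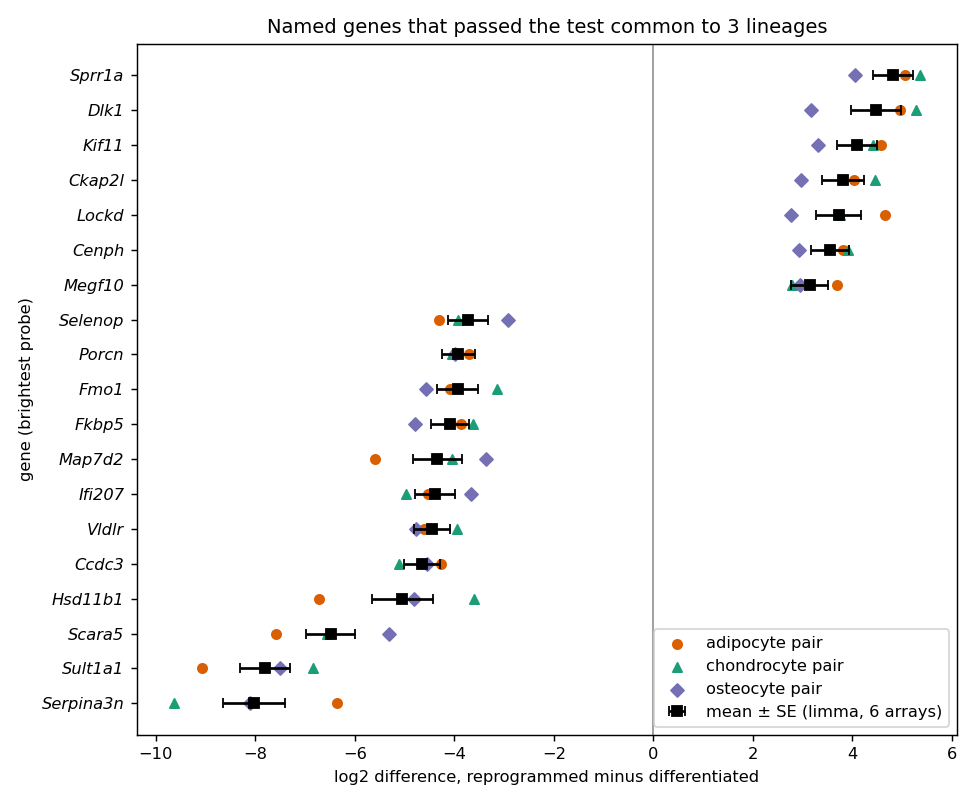
Log2 difference, reprogrammed minus differentiated, for the 19 named genes that passed the test common to 3 lineages. Coloured points are the 3 pairs and black squares the mean with its limma standard error, from Serpina3n at -8.03 to Sprr1a at 4.82.

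Of the gene lists, the cell cycle genes lay highest after reprogramming, with a median log2 change of 3.21 over 23 measured members. All 23 lay higher; 1, Kif11, rose in the test over all probes and 23 rose adjusted over the list alone. Top2a, the DNA topoisomerase of mitosis, lay 4.79 higher (adjusted p = 0.057), and Birc5, or survivin, 4.32 higher (0.065). The list was called by camera (adjusted p = 4.7e-19), but not with an estimated correlation (adjusted p = 0.73) or by fry (0.37). The cell cycle genes also differed between the MSC arrays, with median intensities of 8.64 on MSC 1 and 10.43 on MSC 2 over 26 genes. The 14 hypoxia and glycolysis genes had a median of 0.83 (camera adjusted p = 0.0072), with 0 past the test over all probes and 4 adjusted over the list alone. Pdk1, a pyruvate dehydrogenase kinase, lay 1.82 higher and Ldha, lactate dehydrogenase, 1.44 higher. The 12 adipocyte markers had a median of -1.58 (camera adjusted p = 0.033), with 0 past either test; the adipocyte pair carried it, as medians over the list were -3.83, -0.20 and 0.08 in the adipocyte, chondrocyte and osteocyte pairs. Neither list was called with an estimated correlation (adjusted p = 0.73 for both).

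The other 17 lists were not called (camera adjusted p from 0.11 to 0.75), and their members were counted with the same test. Median changes were 1.35 for 8 smooth muscle and pericyte genes, 0.65 for 16 extracellular matrix genes, 0.58 (0.11 with the limits) for 3 pluripotency genes and 0.41 for 4 chondrocyte markers. They were 0.36 for 9 housekeeping genes, 0.33 for 11 osteoblast and osteocyte markers, 0.32 for 15 stromal genes, 0.25 for 5 genes of DNA methylation and 0.25 for 14 genes of the unfolded protein response. They were 0.18 for 10 cholesterol synthesis genes, 0.02 for 16 Hox genes, 0.01 for 15 interferon-stimulated genes and -0.13 for 10 imprinted genes. They were -0.15 for 12 p53 target genes, -0.22 for 18 immediate-early genes, -0.62 (-0.15 with the limits) for 4 neutrophil and B cell markers and -1.89 for 4 macrophage markers. The chondrocyte pair carried the last value, as medians over all 17 macrophage markers were -0.05, -7.91 and -0.07 in the adipocyte, chondrocyte and osteocyte pairs. The mean had the other sign for the unfolded protein response, interferon-stimulated and imprinted lists. Adjusted over the list alone, 2 methylation genes (1 of them Uhrf1), 2 immediate-early genes, 1 chondrocyte marker, 1 muscle gene, 1 stromal gene and 1 imprinted gene rose. Likewise 2 p53 targets, 1 immediate-early gene, 1 imprinted gene and 1 neutrophil marker fell. Dnmt1, the maintenance methyltransferase, changed by 1.60 (adjusted p = 0.16) and Dnmt3b by -0.07 (0.95), while Dnmt3a was not detected on any array. Pdgfra and Pdgfrb, the receptors of platelet-derived growth factor, changed by -0.63 (0.36) and 0.89 (0.45).

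By limma, 49 of 17728 probes passed (24 higher, 25 lower), covering 34 genes and 11 probes without a symbol. All 49 moved the same way in each pair, and 3491 probes had an unadjusted p under 0.05. The smallest adjusted p was 0.034, so the count lay near the threshold. It was 0 without background correction and with a constant offset in place of negative controls, both with 50 added in place of 16. Without the detection filter and with the in vivo osteocyte pair added it was 0 too. It was 225 without the adipocyte pair, 340 without the osteocyte pair and 343 without the lineage block, and 75th percentile scaling gave 62 (23 higher, 39 lower).

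The test of differentiated populations against MSC addressed what 3 lineages shared. Fgfr2, a receptor of fibroblast growth factors, rose by 3.86 ± 0.31 on the log2 scale (SE, 3 arrays against 2; adjusted p = 0.015). Fkbp5 rose by 4.48 ± 0.39 (0.015) and Serpina3n by 8.14 ± 0.82, at least 130-fold (0.033). Genes near the threshold that did not pass were Sult1a1 at 6.60 (at least 73.2-fold), Usp2, a ubiquitin protease under clock control, at 3.71, Tns1 at 3.64 (at least 9.80-fold), Tsc22d3, a leucine zipper induced by glucocorticoid, at 3.18, and H2bc4 at 2.71 (adjusted p = 0.11 for each). On the lower side Pclaf, a partner of PCNA, had -4.39 (at least 16.4-fold), Kif11 -3.47, Kif18b -3.35 (at least 6.93-fold), Ckap2l -3.27, Sprr1a -3.26, Egr3 -2.76, Kirrel3 -2.59 and Nrn1 -2.42, with adjusted p from 0.11 to 0.16. Kif11, Ckap2l, Sprr1a and Kirrel3 were not detected in differentiated populations and were at least 6.33-fold, 6.32-fold, 6.41-fold and 3.00-fold lower.

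The 23 cell cycle genes had a median of -2.51 against MSC, and all 23 lay lower. No member fell in the test over all probes and 21 fell adjusted over the list alone. Camera called the list (adjusted p = 9.4e-21), but not with an estimated correlation (adjusted p = 0.71). The 13 adipocyte markers had a median of 2.06, or 1.44 with members lacking on 1 side at their limit (camera adjusted p = 0.010), and this was not kept with an estimated correlation (adjusted p = 0.71). Over the list, medians were 3.74, 0.19 and -0.03 on the adipocyte, chondrocyte and osteocyte arrays. On the chondrocyte array 17 of 17 macrophage markers lay above MSC, and the 6 of them in this test had a median of 1.86 (0.091). The 3 osteoclast markers had a median of -0.08 (0.86), and the other lists were not called.

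By limma, 3 of 18131 probes rose and 0 fell, with 568 higher and 1001 lower at an unadjusted p under 0.05. The count was 0 without MSC 1, without MSC 2, without the chondrocyte arrays, with a lineage block, and with the in vivo arrays added, 1 without the osteocyte arrays and 11 without the adipocyte arrays.

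The test of reprogrammed populations against MSC addressed what still set them apart. No gene passed. The spread of this fit also held the differentiated arrays, whose lineages differ from each other. That could hide differences, so the lack of calls does not show likeness to MSC. On the higher side Nefm stood at 2.57 ± 0.52 (SE; 3 arrays against 2), at least 5.24-fold, Crabp1, a retinoic acid binding protein, at 1.61 ± 0.50, and Sprr1a at 1.57 ± 0.53. Fhl3, Pgap4, Ccsap, Basp1 and Tuba3a had 1.12 (at least 1.24-fold), 0.99 (at least 1.58-fold), 0.99 (at least 1.73-fold), 0.95 (at least 1.66-fold) and 0.94. On the lower side Stc1, or stanniocalcin, had -2.49 ± 0.98, at least 5.05-fold, and Egr2, an immediate-early transcription factor, -1.63 ± 0.54. Nfkbiz, Porcn, Epha7, Rab3d, Arhgap20 and Accs had -1.27, -1.12, -1.09 (at least 2.07-fold), -1.06, -1.03 (at least 1.77-fold) and -0.98. The adjusted p was 1.0 for each.

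Cell cycle genes had a median of 0.60 over 23 members, all higher than the MSC mean (camera adjusted p = 7.5e-08). Over 26 genes the median intensity was 10.47, 10.60 and 9.45 in reprogrammed adipocytes, chondrocytes and osteocytes. It was 8.64 on MSC 1 and 10.43 on MSC 2, so the excess rested largely on MSC 1. By these medians reprogrammed adipocytes and chondrocytes lay near MSC 2, and reprogrammed osteocytes below it. The 14 hypoxia and glycolysis genes had 0.50 (0.0019). The 15 interferon-stimulated genes had -1.36 (1.5e-04), with Ifit3 at -2.24 and Isg15, a ubiquitin-like protein, at -1.36. None of these was called with an estimated correlation (adjusted p = 0.80 for each), and 0 members passed over all probes or adjusted over the list alone. The difference of MSC 2 from MSC 1 had a median of 1.65 for the cell cycle genes and -3.30 for the interferon-stimulated genes. By limma 0 of 18131 probes passed, and 46 lay higher and 26 lower at an unadjusted p under 0.05. Together these were 0.40% of probes. With only the reprogrammed and MSC arrays in the fit, 0 passed and 248 of 17009 had an unadjusted p under 0.05. On simulated data of the same layout the test recovered 1.49% of changes of 1 log2 unit, 35.8% of changes of 2 and 93.9% of changes of 4. Of unchanged simulated probes 4.85% had a p under 0.05, against 0.40% of the real probes. The simulated noise thus differs from that of the arrays, and these rates may not hold for them.

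Single populations had no replicate and were described against both MSC arrays without a test. On the differentiated adipocyte array Lcn2, the lipocalin secreted by fat and inflamed tissue, was at least 702-fold higher than MSC. Ces1d, a carboxylesterase, was at least 378-fold higher, Cidec, a lipid droplet protein, at least 371-fold, Gsta3 at least 231-fold and Cyp2e1 at least 92.2-fold. Adipoq, which encodes adiponectin, lay at 14.68 log2 units against 6.40 and 7.89 in MSC. Of 18 adipocyte markers, 15 were at least 2-fold higher, with a median of 3.74, or 3.40 with the lower limits. Emp1 and Timp1 had -5.17 and -5.09, and Gpr176, Col1a1 and Cemip were at least 26.7-fold, 21.6-fold and 13.7-fold lower. The medians were -1.92 for 17 extracellular matrix genes, -1.44 (-1.11 with the limits) for 11 smooth muscle and pericyte genes and 0.89 for 10 cholesterol synthesis genes. The last 2 lists moved with the MSC array, with -2.10 and 1.27 against MSC 1 alone and -0.64 and 0.55 against MSC 2 alone. In all, 1775 probes were at least 2-fold higher and 1717 lower than both MSC arrays.

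On the differentiated chondrocyte array the genes farthest above MSC were macrophage genes. Ms4a6d was at least 729-fold higher, Fcer1g, a subunit of Fc receptors, at least 674-fold, and Laptm5 at least 516-fold. The complement genes C1qc and C1qb were at least 468-fold and 459-fold higher. All 17 macrophage markers were at least 2-fold higher, with a median of 7.94, or 7.15 with the lower limits. Comp, a cartilage matrix protein, lay at 13.74 and was not detected in MSC, and Fmod and Chad, cartilage matrix proteins too, lay at 12.15 and 8.23. Col2a1, the main cartilage collagen, lay at 8.26 against 7.80 and 9.45 in MSC, and the 8 chondrocyte markers had a median of 0.05. Sfrp2, Plac8 and Lmnb1 had -6.24 (-6.83 against MSC 1 and -5.65 against MSC 2), -5.27 and -4.87, and Cxcl1 and Smpd3 were at least 40-fold and 19.2-fold lower. Probes at least 2-fold from both MSC arrays numbered 2454 higher and 2205 lower.

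On the differentiated osteocyte array Serpina3n was at least 143-fold higher than MSC, Aldh1a7, an aldehyde dehydrogenase, at least 164-fold, and Cldn11, a tight junction protein, at least 88.1-fold. Msln and Fam107a were at least 42.5-fold and 35.5-fold higher. Selp had -4.63, and Tgfbi, Sdc3, Aoc3 and Col2a1 were at least 35.1-fold, 22.0-fold, 21.4-fold and 8.54-fold lower. Against MSC 1 alone Selp had -3.90 and Tgfbi, Aoc3 and Col2a1 were at least 17.9-fold, 43.9-fold and 4.81-fold lower, and against MSC 2 alone these were -5.37, 68.8-fold, 10.4-fold and 15.2-fold. Bglap2, an osteocalcin gene, lay at 8.77 against 5.91 on MSC 1 and no detection on MSC 2, while the 12 osteoblast and osteocyte markers had a median of -0.19. The cholesterol synthesis genes had -0.77. The interferon-stimulated genes had 0.58, a value whose sign depended on the MSC array, at -1.10 against MSC 1 and 2.02 against MSC 2. The array had 769 probes higher and 578 lower.

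In vivo osteocytes, like the differentiated chondrocytes, had macrophage genes farthest above MSC. Laptm5 was at least 615-fold higher, Fcer1g at least 545-fold, C1qb at least 502-fold, C1qc at least 459-fold and Bcl2a1d at least 372-fold. The macrophage markers had a median of 7.47, or 7.01 with the lower limits. Bglap2 lay at 13.95 and Bglap at 12.20, and 7 of 12 osteoblast and osteocyte markers were at least 2-fold higher, with a median of 1.42. Plac8 had -7.36, and Itih2, Smoc1, Selp and Tm7sf3 were at least 74.0-fold, 58.1-fold, 34.8-fold and 23.8-fold lower, with Selp at least 20.9-fold against MSC 1 and 57.9-fold against MSC 2. The array had 2168 probes higher and 1876 lower. Cell cycle genes had medians of -2.97, -3.11, -2.05 and -1.55 on the adipocyte, chondrocyte, osteocyte and in vivo osteocyte arrays, or -2.47, -2.58, -1.57 and -1.55 with the limits. Against MSC 1 alone these medians were -2.20, -2.25, -0.98 and -0.72, and against MSC 2 alone -3.83, -3.75, -2.76 and -2.29.

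Reprogrammed populations had the following probes at least 2-fold from both MSC arrays: 34 higher and 150 lower in adipocytes, 68 and 105 in chondrocytes, and 277 and 97 in osteocytes. These counts depended on the MSC arrays: reprogrammed adipocytes, chondrocytes and osteocytes had 3508, 4061 and 1766 probes against MSC 1 alone and 357, 244 and 2178 against MSC 2 alone, and differentiated osteocytes 2089 and 4501. The MSC arrays themselves differed at 2856 probes when 1 was set against the other. In reprogrammed adipocytes Il11, an interleukin, was at least 4.07-fold higher, Nefm at least 6.69-fold, Tmem176a 4.56-fold, Igsf5 at least 2.54-fold and Col2a1 5.40-fold. Against MSC 2 alone Nefm was 4.26-fold and Col2a1 3.04-fold higher. Gpx3 had -4.57, and Igf2, an imprinted growth factor, Bmp4, Agt and Stc1 were at least 18.7-fold, 12.2-fold, 10.3-fold and 8.94-fold lower. These limits rested in large part on MSC 1: they were 73.4-fold, 17.7-fold, 17.8-fold and 13.4-fold against it, and 4.75-fold, 8.37-fold, 5.90-fold and 5.97-fold against MSC 2. In reprogrammed chondrocytes Nefm was at least 5.66-fold higher (3.60-fold against MSC 2 alone), Cadm1 at least 3.34-fold, Crabp1 3.31-fold, Eno3 3.28-fold and Hoxb7 at least 2.01-fold, while Hp, Ccn5, Aldh1a2, Agt and Stc1 lay at -4.43, -3.66, -3.40, -3.18 and -3.16. For these 5 genes the values were -6.29, -4.95, -4.38, -3.98 and -3.74 against MSC 1 alone and -2.57, -2.37, -2.42, -2.38 and -2.58 against MSC 2 alone. In reprogrammed osteocytes Gsk3a, Dpep1, Crabp1 and Creb3l1 were 5.45-fold, 4.86-fold, 4.67-fold and 4.62-fold higher and Rps23rg1 at least 2.18-fold. Ptx3, Rpap3 and Shf had -1.96, -1.83 and -1.62, and Apol10b and Prr7 were at least 4.72-fold and 2.67-fold lower. Adipoq was not detected in reprogrammed adipocytes. The interferon-stimulated genes had medians of -2.04, -2.00 and 0.63 in reprogrammed adipocytes, chondrocytes and osteocytes, or -1.32, -1.48 and 0.63 with the limits. These medians depended on the MSC array, with -3.85, -3.84 and -0.89 against MSC 1 alone and -0.40, -0.42 and 1.90 against MSC 2 alone, so the sign in osteocytes was not fixed.

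Treated in vivo osteocytes had 1608 probes higher and 1438 lower than both MSC arrays. Ptgis, prostacyclin synthase, was at least 257-fold higher, Upk3b, a uroplakin, at least 66.8-fold, Sdr39u1 at least 56.3-fold and Ces2g at least 48.6-fold. Eif2s3y, a gene of the Y chromosome, was at least 54.2-fold higher. Sfrp2, a secreted Wnt antagonist, was at least 122-fold lower, Grb10, an imprinted adaptor, at least 99.4-fold, Kng1 at least 87.2-fold and Casp1 at least 81.8-fold, with Thbs2 at -6.79. Against MSC 2 alone Sfrp2, Kng1 and Casp1 were at least 81.1-fold, 36.2-fold and 48.2-fold lower, against 184-fold, 210-fold and 139-fold for MSC 1. Macrophage markers had a median of -0.03, interferon-stimulated genes -2.24 (-1.75 with the limits), cell cycle genes 0.62 and genes of DNA methylation 1.10 (0.85). The interferon-stimulated genes had -3.71 against MSC 1 and -0.51 against MSC 2, and the cell cycle genes 1.40 and -0.04, so the second value rested on MSC 1 alone. Xist, the transcript of the inactive X chromosome, was not detected on this array and lay between 7.30 and 9.36 on the other 9. The Y-linked genes Eif2s3y, Kdm5d and Uty lay at 11.28, 8.38 and 6.16. On the untreated in vivo osteocyte array Eif2s3y lay at 7.34 and Uty at 5.70, and no Y-linked gene was detected on the other arrays. Hoxc10 was not detected here and lay between 8.66 and 10.94 elsewhere, while Hoxb9, detected on this array alone, lay at 7.86.

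**Figure D3:**
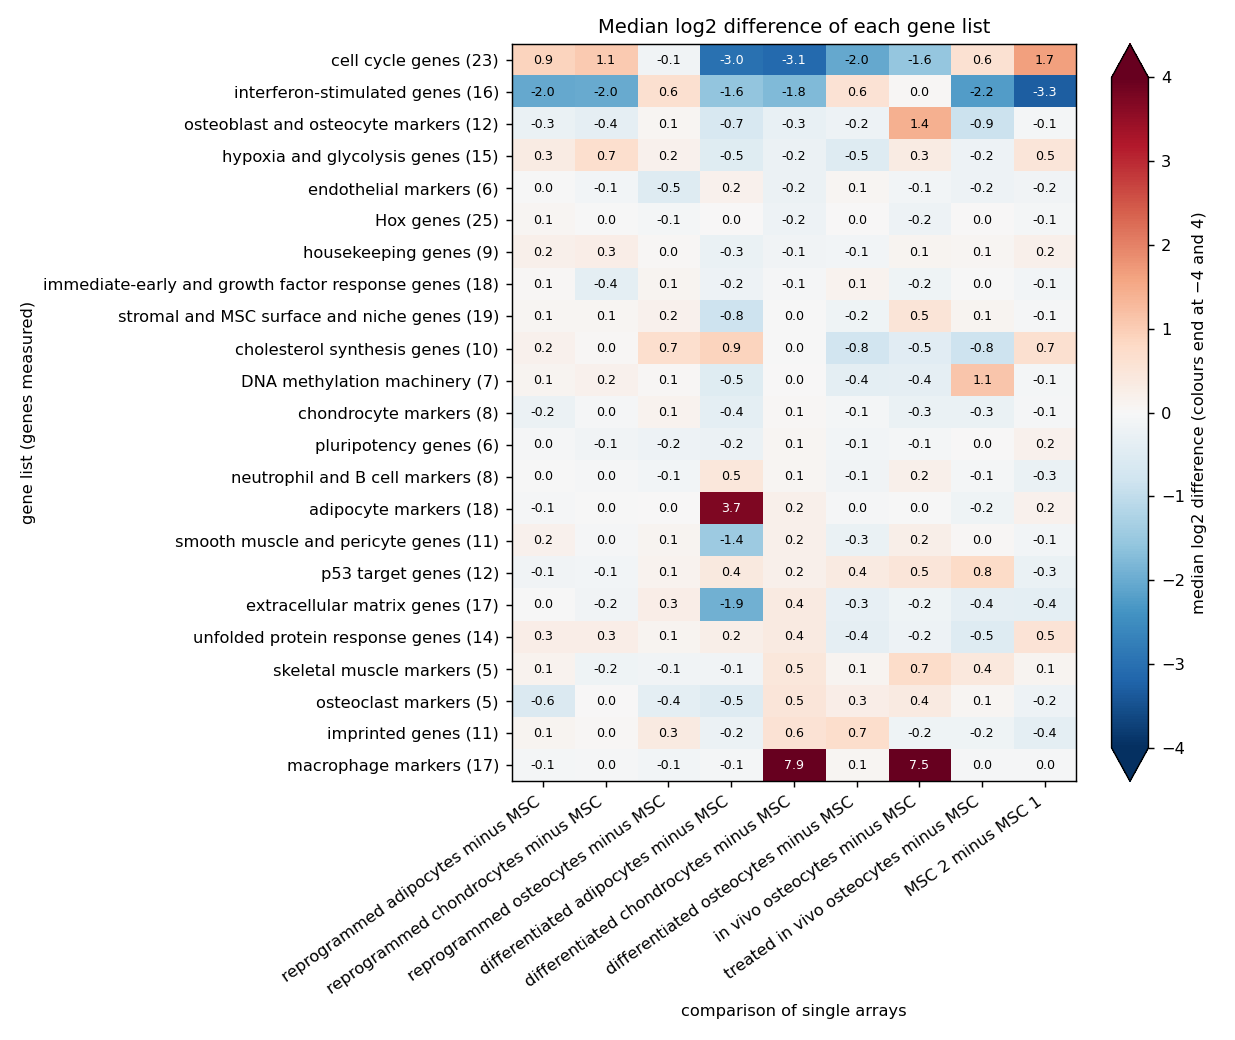
Median log2 difference of each gene list with at least 5 measured genes, for each population minus the mean of the MSC arrays and for MSC 2 minus MSC 1, as colour and number. Macrophage markers stood at 7.94 and 7.47 on the differentiated chondrocyte and in vivo osteocyte arrays, and adipocyte markers at 3.74 on the differentiated adipocyte array.

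The 6 endothelial markers with a signal had medians from -0.52 to 0.18, and the 5 skeletal muscle markers from -0.18 to 0.72. Erythroid markers had 0 members detected on any array. Germline genes under DNA methylation had 3 measured members with medians from -0.65 to 0.41. Imprinted genes reached 0.71 in differentiated osteocytes (0.06 with the limits; 0.27 against MSC 1 alone) and the p53 target genes 0.78 in treated in vivo osteocytes, where the 4 sex-linked genes had 2.29 (1.75). Nes, a marker of perivascular stroma, lay at 8.88 in in vivo osteocytes, and Thy1 at 9.99 there and 9.79 after treatment, while Thy1 was not detected in MSC.

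The pairs of single arrays gave the difference between the arrays of each lineage. In the adipocyte pair Lcn2 was at least 690-fold lower after reprogramming, Adipoq at least 563-fold, Cidec at least 384-fold, Ces1d at least 371-fold and Sult1a1 at least 257-fold. Ankrd1 was at least 115-fold higher, Pclaf at least 42.4-fold, Col2a1 at least 39.2-fold, Top2a at least 39.1-fold and Prkg2 at least 36.2-fold. Adipocyte markers had a median of -3.83 (-3.50 with the limits), cell cycle genes 3.86 (3.33) and extracellular matrix genes 1.49, and 3260 probes were at least 2-fold higher and 3025 lower. In the chondrocyte pair Ms4a6d was at least 822-fold lower, Fcer1g at least 760-fold, Laptm5 at least 582-fold, C1qc at least 528-fold and C1qb at least 517-fold. The prolactin family genes Prl2c4, Prl2c3 and Prl2c2, close paralogs whose probes were not separated here, were 184-fold, 182-fold and 117-fold higher, Selp was 60.3-fold and Pclaf at least 48.8-fold. Macrophage markers had a median of -7.91 (-7.46 with the limits) and cell cycle genes 3.92 (3.65), with 3997 probes higher and 3600 lower.

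In the osteocyte pair Aldh1a7 was at least 185-fold lower, Serpina3n at least 157-fold, Sult1a1 at least 149-fold, Cldn11 at least 96.7-fold and Msln at least 46.6-fold. Tnc, or tenascin C, was at least 34.7-fold higher, Col2a1 at least 27.0-fold, Selp 22.5-fold, Crabp1 at least 18.8-fold and Tgfbi at least 17.7-fold. Cell cycle genes had a median of 1.73 (1.67 with the limits) and cholesterol synthesis genes 1.37, with 2106 probes higher and 1888 lower. The in vivo osteocyte pair differed in Xist (8.68 untreated, not detected treated) and Eif2s3y (7.34 and 11.28), so its arrays may hold cells of different animals. In this pair Laptm5, Fcer1g, C1qb, C1qc and Mpeg1 were at least 668-fold, 592-fold, 545-fold, 498-fold and 375-fold lower on the treated array. Upk3b, Klra4, Smoc1, Tm7sf3 and Cxadr were at least 72.4-fold, 58.3-fold, 50.6-fold, 39.7-fold and 31.7-fold higher. Macrophage markers had a median of -7.72 (-7.01 with the limits), osteoblast and osteocyte markers -3.22 (-2.79) and cell cycle genes 2.12, with 3245 probes higher and 2985 lower.

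**Figure D4:**
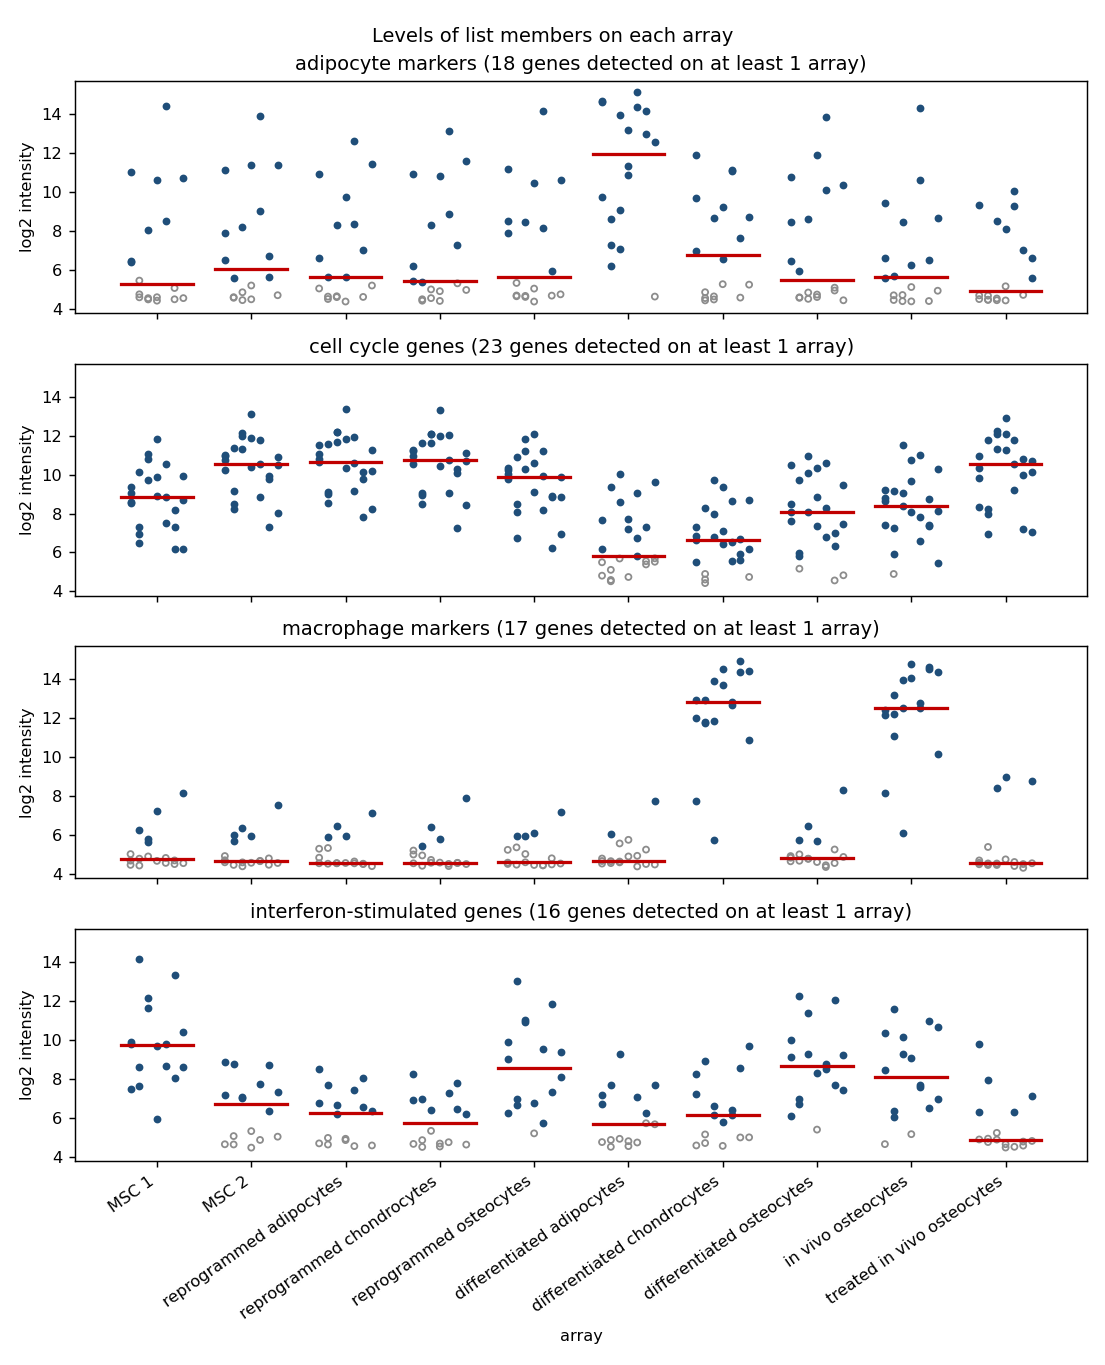
Log2 intensity of each member of 4 gene lists on each array. Filled points were detected, open points were not, and red lines are medians. Fcer1g and the other macrophage markers stand high on the differentiated chondrocyte and in vivo osteocyte arrays, with Fcer1g at 14.92 and 14.61.

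The changes of different lineages were compared across the same 22172 probes, with no p since probes are not independent replicates. Pearson r (Spearman rho) was 0.365 (0.352) for adipocytes with chondrocytes, 0.417 (0.382) for adipocytes with osteocytes and 0.323 (0.287) for chondrocytes with osteocytes. The in vivo pair had 0.542 (0.422) with chondrocytes, the pair of lineages whose starting arrays carried macrophage transcripts, 0.175 (0.200) with adipocytes and 0.141 (0.157) with osteocytes. The difference of MSC 2 from MSC 1 had r of 0.390, 0.369, 0.311 and 0.237 with the adipocyte, chondrocyte, osteocyte and in vivo pairs. Except for the in vivo pair these lay close to the r between lineages, so part of the common change may be of the kind that parts the MSC arrays. In the deposited order MSC 1 stands with the differentiated adipocyte and chondrocyte and untreated in vivo arrays. MSC 2 stands with the reprogrammed adipocyte and chondrocyte and treated in vivo arrays. Whether these sets were separate runs is not given. Both osteocyte arrays stand outside these sets. A difference between the sets would thus not enter the change of the osteocyte pair, whose r was 0.311. The difference between a starting population and MSC 1 was then followed in its reprogrammed or treated population, measured on MSC 2. The median share removed was 100% in adipocytes (5125 probes), 98.9% in chondrocytes (6901), 89.7% in osteocytes (2089) and 67.5% in treated in vivo osteocytes (6251). The starting array enters the choice of probes and both sides of this ratio, so its noise pulls the share towards 100%. The chondrocyte and in vivo starting arrays carried macrophage transcripts that lay near the MSC level afterwards. Their loss counts there as difference removed. No reference value from an unrelated array was taken, and the shares alone do not show a return to MSC. With the MSC arrays exchanged the shares were 123%, 114%, 126% and 82.1%, so they varied with the MSC array by more than the lineages differed among adipocytes, chondrocytes and osteocytes.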

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

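The results in this part were picked by a rule set after list values had been seen: a list median in the upper 2.5% of matched random lists in 1 pair and in the lower 2.5% in another. The cholesterol synthesis genes had a median log2 difference of 1.37 after reprogramming in osteocytes (percentile 100), and of -0.74 in adipocytes (1.75) and -0.61 in treated in vivo osteocytes (1.88). The hypoxia and glycolysis genes had 1.04 in chondrocytes (99.88) and -0.84 in treated in vivo osteocytes (0.14). What picked them was a difference between lineages in opposite directions. The difference was not tested, since each side was 1 array.

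For macrophage transcripts the first test below was written before its list was looked at, and the other 2 after the pattern was seen. If the differentiated chondrocyte and in vivo osteocyte cultures both held cells of the macrophage lineage, at least 80% of a further macrophage list would lie 4-fold above both MSC arrays on both; 19 of 19 genes did (100%). If the arrays were of macrophages alone under a wrong label, matrix genes would lie over 3 log2 units below MSC. Their medians were 0.17 in differentiated chondrocytes and -0.88 in in vivo osteocytes. If differentiation as such raised these genes, adipocytes and osteocytes would carry them; the medians of 17 markers were -0.073 in adipocytes and 0.070 in osteocytes. All 17 markers of the first list were already detected on both arrays. The outcome of the first test was thus likely beforehand and adds little. The values may reflect a mixture with macrophage-lineage cells, by culture or by handling, which the arrays do not separate.

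For the treated in vivo osteocyte array all tests were chosen after the result was seen. Male cells would lack Xist and carry Y-linked genes, and would come from a different animal than the MSC. Both MSC arrays had Xist and no detected Y-linked gene. On the treated array 0 of 4 Xist probes and 3 Y-linked genes were detected. A different female animal would not be seen in this way. Xist lay -3.94 from MSC, a value below detection, and at least 8.36-fold lower as a lower limit. Release of X inactivation in female cells would leave Y-linked genes undetected; Eif2s3y lay 6.74 above the nearer MSC array, where it was not detected, and at least 54.2-fold above MSC as a lower limit. A Hox change made by the treatment in every lineage would recur elsewhere, and 1 of 15 Hox genes did (6.67%). The labels do not say that the reprogrammed populations had the same treatment. The test thus cannot decide whether the treatment changed Hox genes in the in vivo cells. Untreated in vivo osteocytes had Xist at 8.68 and Eif2s3y at 7.34, against no detected Xist and Eif2s3y at 11.28 on the treated array. The arrays thus differ in sex-linked transcripts, and their contrast cannot be read as treatment alone. It could be a contrast of animals or body sites as well as of treatment.

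For the interferon-stimulated genes in MSC the first test was written before its list was looked at and the other after. If the cultures differed in interferon response, a further list would lie at least 1 log2 unit higher in MSC 1; the median of 18 genes for MSC 2 minus MSC 1 was -2.45. If the authors' normalisation made the difference, it would near 0 in the intensities before that step; the median there was -3.38, against -3.30. As the first list already stood at -3.30, the outcome of the first test was likely beforehand and adds little. The lower values of these genes in reprogrammed adipocytes and chondrocytes than in the MSC mean could reflect the MSC 1 culture alone.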

How the results depend on the processing

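The count for reprogrammed minus differentiated, 49 in the fit reported, was 0 without background correction, 0 with a constant offset in normexp, 0 without a detection filter and 0 with the in vivo osteocyte pair added. It was 12 with 1 probe per gene, where fewer probes were tested, 14 with all 8 arrays, 90 with the value table intensities, 154 with detection on at least 3 arrays, 168 with an intensity trend and 343 without the lineage block. With each lineage left out it lay from 47 to 340. The count for differentiated minus MSC, 3 in the fit reported, was 1 without a detection filter, 0 with in vivo arrays added, 0 with only the states compared, 0 with a lineage block, 0 with an osteocyte batch term, and 0 to 11 with a lineage or an MSC array left out; a lone MSC array is assumed to vary like the other groups. Reprogrammed minus MSC stayed at 0 throughout, with 12 to 738 probes at an unadjusted p under 0.05. The cause of these changes was not tested.

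Counts of probes 2-fold from both MSC arrays are given in the order differentiated adipocytes, chondrocytes, osteocytes, in vivo osteocytes, reprogrammed adipocytes, chondrocytes, osteocytes and treated in vivo osteocytes. Without background correction they were 1623, 1956, 468, 1698, 44, 33, 69 and 955. With a constant normexp offset they were 2229, 2771, 686, 2376, 67, 51, 126 and 1481. At 1.5-fold they were 6289, 8209, 3391, 7444, 1033, 1153, 1875 and 6311, and at 4-fold 1031, 1392, 282, 1218, 13, 11, 9 and 698. With limma and a term per population, on 1 residual degree of freedom, they were 0, 588, 0, 518, 0, 0, 0 and 0. With 1 MSC array left out they lay at 5125 to 6042, 6901 to 7100, 2089 to 4501, 6251 to 6502, 357 to 3508, 244 to 4061, 1766 to 2178 and 4475 to 6262.

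Counts for the adipocyte, chondrocyte, osteocyte and in vivo pairs were 3019, 3627, 1417 and 2860 without background correction, 4116, 4942, 2114 and 3939 with a constant normexp offset, 10052, 11943, 8367 and 10567 at 1.5-fold, and 1893, 2474, 656 and 1987 at 4-fold. On probes detected on all 10 arrays, the mean r with MSC minus r with the origin was 0.133 in adipocytes, 0.0367 in osteocytes and 0.0153 in the in vivo pair, against 0.0946, 0.0319 and 0.0460. With the MSC arrays exchanged the share removed was 1.23, 1.14, 1.26 and 0.821, and for the in vivo pair it was 0.800 without background correction and 0.826 at 4-fold. The agreement of lineages kept its values throughout.

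Among named genes and lists, 2335 values stayed the same under an alternative, 658 moved, 149 lost and 24 gained the threshold, and 1 turned: imprinted genes in reprogrammed osteocytes had -0.0487 with 75th percentile scaling, against 0.35. That 1 does not count list medians whose sign depended on the MSC array, such as the interferon-stimulated genes in reprogrammed osteocytes. No call of a list fixed beforehand was kept with an estimated correlation. The median of all detected probes was 0.11 in the chondrocyte pair as reported. Scaling to the 75th percentile put it at -0.18 in the osteocyte pair and 0.11 in differentiated osteocytes, and the value table intensities put it at 0.28 in differentiated adipocytes and -0.24 in the adipocyte pair. The value table by its own IDs and a slide block were planned and not run, as the IDs do not match and the files name no slides. Dim probes limit what could be found, with the 75th percentile at 1.84 to 2.36 times background.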

Other observations

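The genes that responded most to differentiation included glucocorticoid targets. A list of 10 glucocorticoid-responsive genes, drawn up after the fall of Fkbp5, Serpina3n and Sult1a1 was seen and before its own values were looked at, was tested for a fall after reprogramming. If glucocorticoid in the differentiation media had raised these genes, the list would fall with a median below -0.5; the median was -1.89 (camera adjusted p = 1.4e-07; adjusted p = 0.098 with an estimated correlation; fry adjusted p = 0.027). Of the 10, 1 fell over all probes and 8 fell adjusted over the list alone. That 1 was among the probes called above, so the list was not fully separate from them. Against MSC the median was 1.62 in differentiated populations (adjusted p = 0.012 with an estimated correlation, fry adjusted p = 0.0015) and -0.16 in reprogrammed populations. The camera and fry p values of this list were adjusted only over the lists drawn up after the first results. These are fewer than the lists fixed beforehand, so the adjustment was less strict and the values are not comparable. The rise and the fall rest on the same differentiated arrays and are not separate support. Part of the change common to the lineages may thus be a response to medium hormone, which the composition of the media would settle and the labels used here do not give.

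Other splits of the 6 arrays into 3 and 3 were planned before the values were seen. If any grouping of these arrays gave such a count, other splits would give as many; 1 of 10 splits, the real one, gave 49 and the highest other gave 0. Only 4 of the splits, the real one included, parted all 3 lineage pairs, and the others are not comparable with it under the block. There are too few splits for a share under 0.05, so this test cannot tell.

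The further interferon-stimulated list had a median of -0.96 for reprogrammed populations against MSC (camera adjusted p = 6.5e-06, and 0.48 with an estimated correlation). These values too were adjusted only over the lists drawn up after the first results. Chi3l3, a macrophage chitinase-like protein, was detected on the differentiated chondrocyte array alone. Pdgfra lay at 12.90 on MSC 1, 13.04 on differentiated osteocytes and 12.46 on reprogrammed osteocytes, and from 8.74 to 10.75 on the other arrays. Igf2 lay at 11.7 on MSC 1 and 7.80 on MSC 2.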
